A study of Mus musculus with 4 samples.

How the data were processed

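Total RNA of the mouse T cell lines TS1 and TS2 was measured on Affymetrix mouse gene arrays, 2 biological duplicates (A and B) per line and 1 array per duplicate. Per the labels' protocols, RNA quality was examined on a Bioanalyzer, and biotinylated cRNA was made with an Ambion whole-transcript expression kit and an Affymetrix terminal labeling kit. Per the submitters' processing notes, Affymetrix Expression Console and RMA were used, with no version stated. The deposited values are intensities on a linear scale, 1 per probe set and array, and the filters and the array's library files are not given in the sources used here. RMA corrects background, normalizes between arrays and summarises the probes of a probe set, which means that a shift shared by most genes of an array is removed from the values. The deposited column medians were 89.0 for TS1 A, 92.5 for TS1 B, 88.6 for TS2 A and 89.9 for TS2 B. The plan made before the data were examined assumed deposited log2 values. The intensities proved linear, from 5.98 to 23157, so log2 of them was taken here and the tests were kept. There were 0 missing or non-positive values, so no pseudocount was needed. The values are used here without detection calls or probe sequences, and the scan day and slide of each array are not analysed here, so signal over background and batches could not be examined.

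Probe sets were named from the platform's annotation table. Of 35556 probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 had none. Symbols were updated by Entrez gene number through a RefSeq gene table of mouse assembly GRCm38.p6, in which 21698 of the single-gene probe sets were found. The single-gene probe set with the highest mean over all 4 arrays stood for each gene, which gave 19939 genes, 998 of them with several probe sets. Probe sets with several or no gene names stayed out of the gene counts. In a fit of all probe sets, 1849 passed, 56 with several genes and 315 with none.

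All 4 arrays entered one linear model with the line as its factor, fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with data.table (version 1.17.8). The model has 2 residual degrees of freedom, and the prior has 3.03. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and a second count required a difference of at least 2-fold. The SD of B minus A over all probe sets was 0.325 in TS1 and 0.282 in TS2, against 0.549 between the line means. A difference of single arrays is noisier than a difference of means. These values cannot show whether the duplicates were separate cultures. The same fit was tested on simulated data with variances drawn from the prior that limma fitted to the real genes, 200 of 19939 genes changed and 20 simulations. It recovered 66.4% of the genes changed by 1 on the log2 scale and 96.3% of those changed by 2, with a mean of 8.1 false calls.

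The 24 gene lists, with 722 genes of which 652 had a single-gene probe set, were written before the data were examined, as were the tests, the rule for named genes and the alternatives. Each list of at least 5 measured genes was tested with limma's camera (preset correlation 0.01), with Benjamini-Hochberg adjustment over the 24 lists. Camera compares a list with all other genes. Members past the threshold were counted over all genes tested and adjusted over the list alone. The alternatives for the lists were camera with an estimated correlation and fry. T cell receptor segments were the genes whose symbols start with the letters of such segments. Tradd, which matches these letters but is no segment, was left out, which left 9.

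Named genes followed a rule. It takes the 10 largest differences in each direction among called genes whose arrays do not overlap, leaving out predicted, clone-like, olfactory and vomeronasal receptor and small RNA symbols, of which 103 were called. It adds up to 4 called members of each list with the largest differences. It always includes Il9r, Il2rg, Cd4, Cd8a, Cd3e, Jak1, Jak3, Stat3, Stat5a, Stat5b, Gata3, Tbx21, Il4, Il9, Pim1, Bcl3 and Socs3. It adds up to 6 called receptor segments. Il2rg and Jak3 are not analysed here. Genes outside the rule are said to be named after their values were seen.

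The alternatives were the replicate letter as a block, each array left out in turn, a prior variance with an intensity trend or robust to outliers, each array centred on its median, quantile normalization again, the dimmest 30% or 50% of probe sets left out, the mean of all probe sets of a gene, no moderation of the variances, an adjusted p under 0.01, and limma's treat against a 2-fold minimum. For the similarity of the arrays, the probe sets in the upper 50% by mean were the alternative. With 1 array of a line left out, the remaining one is assumed to vary like the other line. Fewer residual degrees of freedom are then left, so a call can be lost although the difference hardly moves. The median of all genes moved by 0.024 with centring and by 0.0062 with quantile normalization. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

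For the chromosomes, genes were placed by the RefSeq table, and 10000 random sets of genes matched on mean intensity gave the range expected by chance, over genes with a mean log2 intensity of at least 8. This comparison was not part of the plan made before the data were examined.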

Results

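Gene expression was compared between TS1 and TS2, mouse cell lines that the labels describe as derived from CD4-positive T lymphocytes. Both lines were kept under the same culture conditions, in a medium that contained murine interleukin-9 (IL-9), a T cell growth factor. RNA from 2 biological duplicates of each line, A and B, was hybridised to Affymetrix mouse gene arrays, on which each gene is read by a set of probes. The values are background-corrected and normalized intensities, 1 array per duplicate, and log2 of them was taken here. The median intensity over 35556 probe sets was 89.0 on TS1 A, 92.5 on TS1 B, 88.6 on TS2 A and 89.9 on TS2 B. Of these probe sets, 21789 named 1 gene, and the brightest of each gene gave 19939 genes. The number of arrays limits the precision of every value: an exact two-sided permutation test of 2 against 2 arrays cannot give a p below 0.333. The adjusted p-values of single genes therefore come from limma, which shares variance between genes, with Benjamini-Hochberg adjustment over all 19939 genes. Differences are TS2 minus TS1 on the log2 scale, with their standard error (SE) and n = 2 arrays per line.

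The first question was how close the duplicates lay against the distance between the lines. Across all probe sets, Pearson's r was 0.992 between the TS1 duplicates and 0.994 between the TS2 duplicates. Between arrays of different lines it was 0.969 to 0.976. These correlations run across probe sets, which are not independent replicates. The first principal component, which held 76.8% of the variance, separated the lines. Over one probe set per gene, 221 genes lay at least 2-fold apart between the TS1 duplicates and 123 between the TS2 duplicates.

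The second question was which genes the lines expressed at different levels. TS2 cells had far more transcript of several leukocyte and T cell genes, among them Ptprc, which encodes the leukocyte common antigen CD45, Cd3e, a chain of the T cell receptor complex, and Stat4, a transcription factor activated by interleukin-12. TS1 cells had far more Xist, the RNA that coats the inactive X chromosome, and Peg10, an imprinted gene of retrotransposon origin. In all, 2691 of 19939 genes passed an adjusted p of 0.05, 1006 of them higher in TS2 and 1685 higher in TS1. At least a 2-fold difference was reached by 1035 of them, 448 higher in TS2 and 587 higher in TS1. At least an 8-fold difference was reached by 76 genes higher in TS2 and 85 higher in TS1. The arrays of the lines did not overlap for 58.4% of all genes, against 33.3% by chance. The count of 2691 depended on single arrays: it was 1565 without TS1 B, 980 without TS2 A and 1035 without TS2 B. The same linear model without moderated variances called 0 genes, with 4156 at an unadjusted p under 0.05. Signal over background was not examined, so how large a difference is stays uncertain where a gene is dim in one of the lines.

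**Figure D1:**
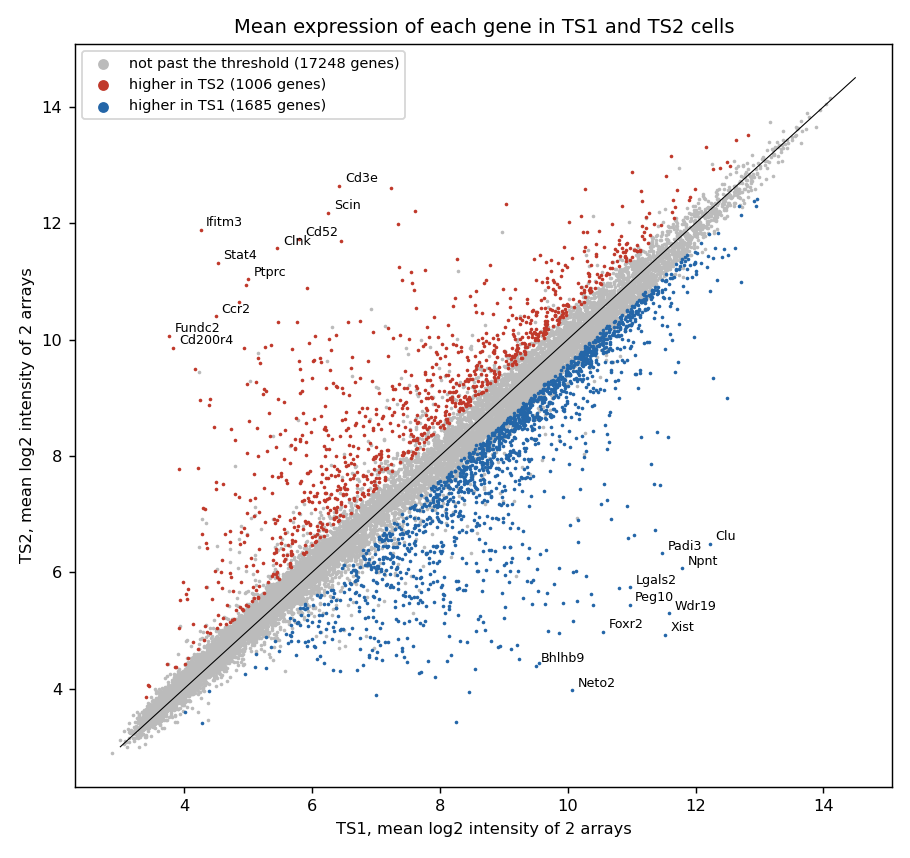
Mean log2 intensity of each of 19939 genes in TS1 (x axis) and TS2 (y axis), 2 arrays per line, with 1006 genes higher in TS2 in red and 1685 higher in TS1 in blue. The labelled genes are 10 in each direction, chosen by size among called genes after predicted, clone-like, olfactory and vomeronasal receptor and small RNA symbols were left out, from Ifitm3 at 7.62 to Xist at -6.60.

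Among the 10 genes with the largest excess in TS2, predicted and clone-like symbols left out, Ifitm3, an interferon-induced membrane protein, led with a difference of 7.62 (SE 0.31, adjusted p = 0.0005). Its mean log2 intensity was 4.26 ± 0.65 (SD, n = 2) in TS1 and 11.88 ± 0.16 (SD, n = 2) in TS2. Stat4 followed with a difference of 6.79 (SE 0.13, adjusted p = 0.000105), from a TS1 mean of 4.53. Fundc2, a mitochondrial membrane protein gene, differed by 6.30 and Cd3e by 6.21 (SE 0.11, adjusted p = 9.39e-05). Clnk, an adaptor of immune receptor signalling, differed by 6.11, and Ptprc by 6.04 (SE 0.097, adjusted p = 9.39e-05). Ptprc had a log2 intensity of 4.998 ± 0.0051 (SD, n = 2) in TS1 and 11.03 ± 0.11 (SD, n = 2) in TS2. Cd200r4, of the CD200 receptor family, differed by 6.02, and Cd52, a small surface glycoprotein of lymphocytes, by 5.92. Ccr2, a chemokine receptor, differed by 5.91. Scin, which encodes an actin-severing protein, differed by 5.92 (SE 0.76, adjusted p = 0.0118), but its TS1 arrays spread widely (SD 1.69). The call of Scin was lost without TS2 A (adjusted p = 0.0545) and without TS2 B (adjusted p = 0.0572). Ifitm3 and Cd200r4 have close paralogs, so part of their signal is uncertain.

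Among the 10 with the largest excess in TS1 by the same rule, Xist differed by -6.60 (SE 0.11, adjusted p = 9.39e-05). Wdr19, a protein of transport within cilia, differed by -6.30, and Neto2, an accessory subunit of glutamate receptors, by -6.10. Clu, which encodes the secreted chaperone clusterin, differed by -5.74, and Npnt, an extracellular matrix protein, by -5.73 (SE 0.095, adjusted p = 9.39e-05). Foxr2, a forkhead transcription factor, differed by -5.59 and Peg10 by -5.53 (SE 0.088, adjusted p = 9.39e-05). Lgals2, which encodes galectin-2, differed by -5.23 (SE 0.41), Padi3, a peptidylarginine deiminase, by -5.16 and Bhlhb9 by -5.11. The adjusted p of these 10 genes ran from 9.39e-05 for Xist to 0.00285 for Lgals2.

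The lines differed in part of the T cell receptor machinery. Of 41 measured genes of the T cell receptor complex and its signalling, 9 were higher in TS2, 5 were higher in TS1 and 27 did not pass, and adjusted over the list alone 10 and 7 passed. The 27 included genes dim in both lines, such as Cd3d (4.63 to 4.92 over the arrays) and Cd2 (4.96 to 5.39). Others of them were bright in both, such as Lcp2 (11.8 to 12.3). Cd3d, Cd2 and Lcp2 are named after their values were seen. Besides Cd3e and Ptprc, Rasgrp1, an exchange factor that activates Ras, differed by 4.15 (SE 0.15, adjusted p = 0.000405). Sla, an adaptor that dampens receptor signalling, was 24.3-fold higher (SE 0.73 on the log2 scale, adjusted p = 0.0203). The call of Sla was lost without TS2 A (adjusted p = 0.0905), without TS2 B (adjusted p = 0.0845) and with a prior variance robust to outliers (adjusted p = 0.0628). The 5 genes higher in TS1 were Lat, Malt1, Grap2, Prkcq and Tec, which encode adaptors, kinases and, with Malt1, a protease of the pathway and are named after their values were seen. The list was shifted upward in TS2 by camera (adjusted p = 0.0323), but it did not pass with an estimated correlation (adjusted p = 0.240). It also did not pass without TS1 B, where its median difference was 0.077, against 0.087 with all arrays. Camera with an estimated correlation called a shifted list in 0 of 20 simulations of this design. Its result, here and below, therefore cannot count against a list. Cd4 was dim in both lines, with a log2 intensity of 5.37 ± 0.015 (SD, n = 2) in TS1 and 5.21 ± 0.090 (SD, n = 2) in TS2 (difference -0.15, adjusted p = 0.358). Cd8a lay at 5.96 in TS1 and 6.30 in TS2 (difference 0.34, adjusted p = 0.151). Of 9 measured T cell receptor segments, limma called 0, with 1 at an unadjusted p under 0.05. That segment, Trbv1, named after its values were seen, differed by 0.76 (SE 0.18, adjusted p = 0.0537). Some of the other segments belong to families of close copies, so their single values are uncertain. One segment passed without TS1 B, with a robust prior variance, after centring or renewed quantile normalization, and with the dimmest 30% or 50% of probe sets left out.

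**Figure D2:**
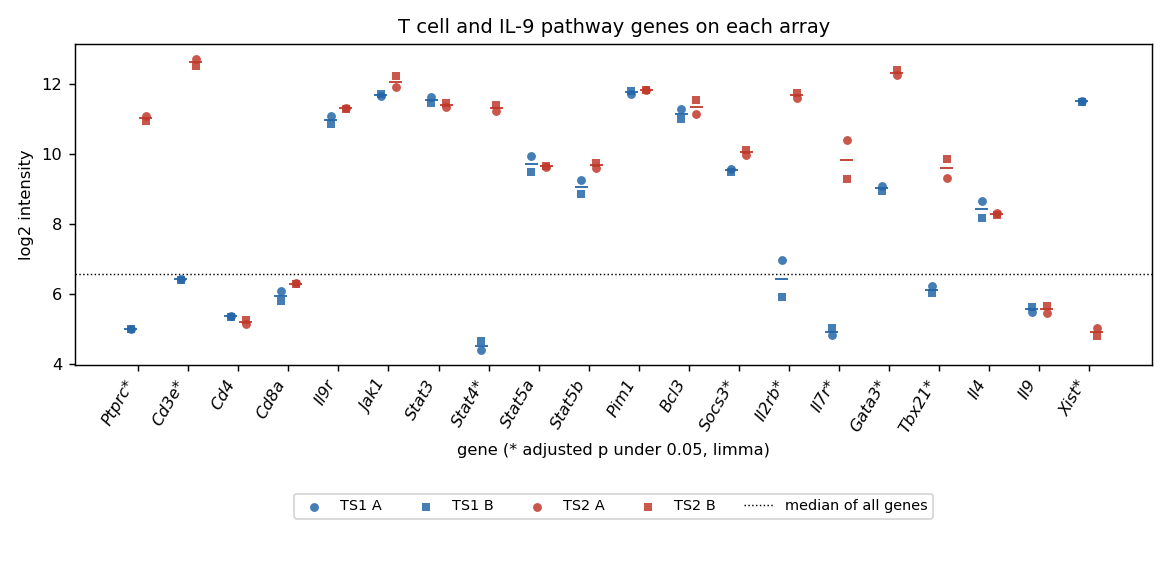
Log2 intensity (y axis) of 20 T cell and IL-9 pathway genes (x axis) on each of the 4 arrays, TS1 in blue and TS2 in red, circles for A and squares for B, short lines for the means and a dotted line for the median of all genes. Ptprc, Cd3e, Stat4 and Il7r differ widely between the lines, while Il9r, Jak1, Stat3 and Pim1 differ by -0.14 to 0.38.

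The receptor for the growth factor in the medium was bright in both lines, and most named genes of its signalling pathway did not pass the test. Il9r, the IL-9 receptor, had a log2 intensity of 10.97 ± 0.16 (SD, n = 2) in TS1 and 11.31 ± 0.035 (SD, n = 2) in TS2, a difference of 0.34 with a 95% interval of 0.055 to 0.63 (adjusted p = 0.119). Jak1, the kinase bound to that receptor, differed by 0.38 (adjusted p = 0.137). Stat3 differed by -0.14 (adjusted p = 0.464), Stat5a by -0.069 (adjusted p = 0.842) and Stat5b by 0.61 (SE 0.16, adjusted p = 0.0691), and these 3 encode transcription factors activated by Janus kinases. Stat5b passed without TS1 A (adjusted p = 0.0302). Pim1, a survival kinase, differed by 0.072 (adjusted p = 0.667) and Bcl3, a regulator of NF-kappa-B, by 0.21 (adjusted p = 0.513). Socs3, a feedback inhibitor of cytokine signalling, was higher in TS2 by 0.52 (SE 0.100, adjusted p = 0.0336). Its call was lost whichever array was left out, with adjusted p = 0.0627 without TS1 A, 0.104 without TS1 B, 0.114 without TS2 A and 0.175 without TS2 B, and with the replicate letter as a block (adjusted p = 0.0818). Il2rg and Jak3 are not analysed here.

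Of 35 measured genes of the JAK-STAT pathway and its feedback, 9 were higher in TS2 and 0 in TS1 by limma (16 and 3 at an unadjusted p under 0.05), and adjusted over the list alone 12 and 2 passed. Next to Stat4, Myc, a growth regulator, was higher by 2.33 (SE 0.14, adjusted p = 0.00157). Cish, a feedback inhibitor, was higher by 1.30 (adjusted p = 0.0256), a call lost without TS2 A (adjusted p = 0.121) and without TS2 B (adjusted p = 0.0905). Ptpn6, a phosphatase, was higher by 1.21 (adjusted p = 0.0315), a call lost without TS1 A (adjusted p = 0.101), TS1 B (adjusted p = 0.0784) or TS2 B (adjusted p = 0.0685). Camera placed the list upward in TS2 (adjusted p = 0.00293), but not with an estimated correlation (adjusted p = 0.240).

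Some receptors and products of other cytokines also differed between the lines. Of 40 measured cytokine receptors, 6 were higher in TS2 and 5 in TS1, the same counts as adjusted over the list alone. Il2rb, a chain of the interleukin-2 and interleukin-15 receptors, was higher in TS2 by 5.25 (SE 0.35, adjusted p = 0.00187). Il7r, the interleukin-7 receptor, was higher in TS2 by 4.92 (SE 0.37, adjusted p = 0.00264). Lifr, the receptor of leukemia inhibitory factor, was higher in TS1 (difference -4.22, SE 0.70, adjusted p = 0.0228). Its call was lost with a robust prior variance (adjusted p = 0.0688), without TS2 A and without TS2 B. The difference of Lifr itself was -4.15 without TS2 A and -4.28 without TS2 B. Ifngr1, the interferon-gamma receptor, was higher in TS2 by 1.92 (adjusted p = 0.0121), a call lost without TS2 A (adjusted p = 0.0557) and without TS2 B (adjusted p = 0.0610). As a list, the receptors did not pass camera (adjusted p = 0.114), nor camera with an estimated correlation (adjusted p = 0.250) or fry in one direction (adjusted p = 0.0691), but they did pass camera without TS1 A (adjusted p = 0.0189), without TS2 A (adjusted p = 0.0486) and with the dimmer 50% of probe sets left out (adjusted p = 0.0116). Of 34 measured cytokines, 4 were higher in TS2 and 0 in TS1 by limma (10 and 0 at an unadjusted p under 0.05), the same counts as adjusted over the list alone. They were Lif, the ligand of Lifr, higher by 3.84 (SE 0.18, adjusted p = 0.000772), Csf1, a macrophage growth factor, by 2.22, Ifng, which encodes interferon gamma, by 1.51, and Tnfsf11 by 1.44. The call of Tnfsf11 (adjusted p = 0.0102) was lost without TS2 A (adjusted p = 0.0563). Il4 differed by -0.13 (adjusted p = 0.677), and Il9 was dim in both lines, at 5.57 in each (difference 0.0043, adjusted p = 0.988). Camera placed the cytokines upward in TS2 (adjusted p = 0.00293), but not with an estimated correlation (adjusted p = 0.240). The share of cytokines called, 11.8%, was below that of all genes, 2691 of 19939.

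Lineage transcription factors of T helper cells were higher in TS2 as a list by camera (adjusted p = 0.00267), but not with an estimated correlation (adjusted p = 0.240). Of 32 measured, 10 were higher in TS2 and 2 in TS1, and adjusted over the list alone 12 and 2 passed. Tbx21, the factor of the type 1 lineage, was higher by 3.47 (SE 0.20, adjusted p = 0.00131), and Gata3, the factor of the type 2 lineage, by 3.30 (SE 0.11, adjusted p = 0.000343). Gata3 had a log2 intensity of 9.03 ± 0.097 (SD, n = 2) in TS1 and 12.33 ± 0.10 (SD, n = 2) in TS2. Ikzf3, a zinc finger factor of lymphocytes, was higher by 3.43. Higher in TS1 were Eomes, a relative of Tbx21, by 7.38-fold (adjusted p = 0.0017) and Runx1, named after its values were seen.

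Camera placed co-stimulatory and co-inhibitory receptors (adjusted p = 0.00139) and chemokine genes (adjusted p = 0.00172) upward in TS2. With an estimated correlation neither passed (adjusted p = 0.240 for each). Of 36 measured co-stimulatory and co-inhibitory receptors, 12 were higher in TS2, 1 in TS1 and 23 did not pass, and adjusted over the list alone 13 and 1 passed. Entpd1, an ATP-degrading enzyme (CD39), was higher by 4.97 (SE 0.16, adjusted p = 0.000358), the inhibitory receptor Cd200r1 by 4.53 and the adhesion receptor Cd226 by 4.03. The activation marker Cd69 was higher by 3.47 (adjusted p = 0.0116), a call lost without TS2 A (adjusted p = 0.0588). The gene higher in TS1 was Nt5e, the AMP-degrading enzyme CD73, named after its values were seen. Of 36 measured chemokines and chemokine receptors, 4 were higher in TS2 and 0 in TS1 by limma (10 and 1 at an unadjusted p under 0.05), the same counts as adjusted over the list alone. Besides Ccr2 these were Ccr8, higher by 2.00 (SE 0.13, adjusted p = 0.0017), Cx3cr1, higher by 1.69, and Ccl3, higher by 2.11 (adjusted p = 0.0155). The share of chemokine genes called, 11.1%, was below that of all genes, 2691 of 19939. Ccl3 lost its call without TS1 A (adjusted p = 0.0579) and without TS1 B (adjusted p = 0.0582).

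Receptors of natural killer (NK) cells and cytotoxic granule genes were higher in TS2 as lists by camera (adjusted p = 0.000519 and 0.00267), but not with an estimated correlation (adjusted p = 0.240 and 0.250). The granule list also did not pass fry in one direction (adjusted p = 0.0691). Of 24 measured NK cell and innate receptors, 9 were higher in TS2 and 2 in TS1, and adjusted over the list alone 11 and 2 passed. Klrk1, the activating receptor NKG2D, was higher by 4.58 (SE 0.17, adjusted p = 0.000405). Lilr4b was higher by 3.13 (adjusted p = 0.0122), Lilrb4a by 3.01 (adjusted p = 0.0163) and Cd244a by 2.70 (adjusted p = 0.0256). Without TS2 A their adjusted p was 0.0513 for Lilr4b, 0.0622 for Lilrb4a and 0.113 for Cd244a, and without TS2 B it was 0.0601, 0.0783 and 0.0972. Lilr4b and Lilrb4a are near-identical copies, so their separate values are uncertain. Of the 24 genes, 18 were higher on TS1 A than on TS1 B, with a median of 0.18. The 2 genes higher in TS1, Fcer1g and Tyrobp, encode signalling adaptors and are named after their values were seen. Of 23 measured cytotoxic granule genes, 7 were higher in TS2 and 1 in TS1, and adjusted over the list alone 10 and 1 passed. Here 16 of the 23 genes were higher on TS1 A than on TS1 B, with a median of 0.12. The median difference between the lines was 0.25. Ctsw, a cathepsin, was higher in TS2 by 2.92 (adjusted p = 0.00735), Nkg7 by 1.89 (adjusted p = 0.0353) and Gzma, granzyme A, by 1.87 (adjusted p = 0.016). Nkg7 lost its call without TS2 A (adjusted p = 0.142), without TS2 B (adjusted p = 0.133) and with a robust prior variance (adjusted p = 0.0571), and Gzma without TS1 A (adjusted p = 0.0533). Serpinb6b, a protease inhibitor, was higher in TS1 by 2.99-fold.

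Interferon-stimulated genes and genes of antigen presentation were higher in TS2 as lists by camera (adjusted p = 6.45e-06 and 0.00267), but not with an estimated correlation (adjusted p = 0.250 and 0.240). Of 33 measured interferon-stimulated genes, 11 were higher in TS2 and 0 in TS1 by limma (18 and 0 at an unadjusted p under 0.05), and adjusted over the list alone 14 and 0 passed. After Ifitm3, the called genes with the largest differences were Ifi203, 4.71 (SE 0.30, adjusted p = 0.00161), Zbp1, a sensor of nucleic acids, 1.91, and Xaf1, 1.75. The TS1 duplicates were apart on this list: 26 of the 33 genes were higher on TS1 A than on TS1 B, by a median of 0.33 over the list, and TS1 A lay on the side of TS2 for 28. Of 23 measured genes of the major histocompatibility complex (MHC) class I and class II pathways, 8 were higher in TS2 and 2 in TS1, and adjusted over the list alone 10 and 2 passed. H2-Q4, a class I gene with close paralogs, was higher by 2.36 (adjusted p = 0.003). Nlrc5, an activator of class I genes, was higher by 1.22 on the brightest of its 19 probe sets, which ranged from 1.20 to 2.63, and Tap1, a peptide transporter, by 1.11 (SE 0.094, adjusted p = 0.00356). Higher in TS1 were Cd1d1, a lipid-presenting molecule, by 6.11-fold (adjusted p = 0.00248) and H2-DMa, named after its values were seen. The class II genes H2-Aa, H2-Ab1, H2-Ea and H2-Eb1, also named after their values were seen, did not pass. Their differences ran from -0.020 to 0.058. The class I genes H2-K1 and H2-D1 had no single-gene probe set and are not analysed here.

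Genes of cholesterol biosynthesis were higher in TS1 as a list by camera (adjusted p = 2.9e-07), but not with an estimated correlation (adjusted p = 0.250). Of 20 measured, 0 were higher in TS2 and 11 in TS1 by limma (0 and 16 at an unadjusted p under 0.05), and adjusted over the list alone 0 and 15 passed. Insig1, a sterol sensor, differed by -1.86 (SE 0.086, adjusted p = 0.000718), Sqle, squalene epoxidase, by -1.19 (SE 0.10, adjusted p = 0.00353), Tm7sf2, a sterol reductase, by -1.41 (adjusted p = 0.00997) and Fdft1, squalene synthase, by -0.99 (adjusted p = 0.0126). Tm7sf2 lost its call without TS2 A (adjusted p = 0.0566) and Fdft1 without TS1 B (adjusted p = 0.0543). The median difference of the list was -0.71. TS2 B minus TS2 A had a median of -0.15 on this list, with 1 of the 20 genes higher on TS2 B.

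Of 21 measured glycolysis genes, 1 was higher in TS2 and 4 in TS1, and adjusted over the list alone 1 and 7 passed. Pfkfb3, a regulator of the pathway, differed by -1.25 (SE 0.085, adjusted p = 0.00194) and Aldoc, an aldolase, by -0.94. Of the enolases, Eno3 was higher in TS2 by 2.11 (adjusted p = 0.00805) and Eno2 was higher in TS1 by 5.34-fold (adjusted p = 0.0256). Eno2 lost its call without TS2 A (adjusted p = 0.0829), without TS2 B (adjusted p = 0.112) and with the replicate block (adjusted p = 0.0569). The remaining gene higher in TS1 was Pfkm, a phosphofructokinase, named after its values were seen. Camera placed the list downward in TS2 (adjusted p = 0.0436), a call lost without TS1 B (adjusted p = 0.141), without TS2 A (adjusted p = 0.100), after quantile normalization (adjusted p = 0.0637), with the dimmest 30% or 50% of probe sets left out (adjusted p = 0.142 and 0.273), with an estimated correlation (adjusted p = 0.534) and with fry in one direction (adjusted p = 0.0710). On TS1 A 5 of the 21 genes were higher than on TS1 B, with a median of -0.16. Of 30 measured genes of amino acid and unfolded protein stress, 3 were higher in TS2 and 5 in TS1, and adjusted over the list alone 3 and 7 passed. Cth, an enzyme of cysteine synthesis, differed by -2.78 (SE 0.20, adjusted p = 0.0022) and Sesn2, a stress-induced protein, by -0.82 (adjusted p = 0.0125). Atf3, a stress-induced transcription factor, was higher in TS2 by 0.93, and Herpud1, of protein degradation at the endoplasmic reticulum, by 0.76 (adjusted p = 0.0182). Sesn2 lost its call without TS2 A (adjusted p = 0.0746) or TS2 B (adjusted p = 0.0704), and Herpud1 without TS1 B (adjusted p = 0.0699) or TS2 A (adjusted p = 0.0916). The others that passed, named after their values were seen, were Cebpb, higher in TS2, and Dnajb9, Creld2 and Hyou1, higher in TS1. Camera placed the list downward in TS2 (adjusted p = 0.0254), a call lost without TS2 B (adjusted p = 0.0513), after quantile normalization (adjusted p = 0.0561), with the dimmest 30% or 50% of probe sets left out (adjusted p = 0.0857 and 0.117) and with an estimated correlation (adjusted p = 0.240).

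Of 31 measured apoptosis regulators, 9 were higher in TS2 and 2 in TS1, and adjusted over the list alone 11 and 2 passed. Casp1, an inflammatory caspase, was higher by 4.49 (SE 0.32, adjusted p = 0.00226), and the death-promoting genes Pmaip1 and Bmf by 1.78 and 1.52. Higher in TS1 were the death receptor gene Tnfrsf10b, by 2.11-fold (adjusted p = 0.0165), and Casp6, named after its values were seen. Bmf (adjusted p = 0.0221) lost its call without TS2 A (adjusted p = 0.101) and without TS2 B (adjusted p = 0.0559), and Tnfrsf10b likewise (adjusted p = 0.0673 and 0.0866). Of 23 measured immediate early and heat shock genes, 6 were higher in TS2 and 2 in TS1, and adjusted over the list alone 7 and 2 passed. The TS2 duplicates were apart on this list, with 16 of the 23 genes higher on TS2 B and a median of 0.11. The median difference between the lines was 0.15. Egr1, an early growth response factor, was higher by 1.80 (SE 0.17, adjusted p = 0.00455), Nr4a1 by 0.999 (adjusted p = 0.0128) and Jund by 0.98 (adjusted p = 0.0104). Nr4a1 lost its call without TS1 B (adjusted p = 0.0505) or TS2 B (adjusted p = 0.0590), and Jund without TS2 A (adjusted p = 0.0595) or TS2 B (adjusted p = 0.0601). Higher in TS1 were Ier3, by 1.97-fold, and Hsph1, a heat shock protein named after its values were seen. Camera gave adjusted p = 0.00267 for the apoptosis regulators and 0.0171 for the immediate early genes, both upward in TS2, and the second call was lost without TS2 B (adjusted p = 0.0513) and with fry in one direction (adjusted p = 0.0531). With an estimated correlation the adjusted p was 0.240 and 0.250.

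Of 45 measured cell cycle genes, 5 were higher in TS2, 2 were higher in TS1 and 38 did not pass, and adjusted over the list alone 7 and 3 passed. The share called over all genes tested, 15.6%, was close to that of all genes, 2691 of 19939. E2f2, a cell cycle transcription factor, differed by -0.82 (adjusted p = 0.017), the kinase Cdk6 by 0.81 (adjusted p = 0.0291), the cyclin Ccne1 by 0.66 (adjusted p = 0.0414) and the checkpoint kinase Bub1b by 0.62 (adjusted p = 0.0484). All 4 calls were lost without TS1 B (adjusted p = 0.0637, 0.0732, 0.104 and 0.131) and without TS2 B (adjusted p = 0.0846, 0.0855, 0.185 and 0.109). Those of Cdk6, Ccne1 and Bub1b were also lost without TS2 A (adjusted p = 0.143, 0.117 and 0.214). With the replicate block, E2f2 (adjusted p = 0.0503) and Ccne1 (adjusted p = 0.0931) lost theirs. Bub1b also lost its call after centring (adjusted p = 0.0582) and quantile normalization (adjusted p = 0.0524). The others that passed, named after their values were seen, were Cdkn2c and Cdc25b, higher in TS2, and Mybl2, higher in TS1. Camera placed the list upward in TS2 (adjusted p = 0.0203), but it did not pass with an estimated correlation (adjusted p = 0.286). It also did not pass without TS2 B, where its median difference stayed at 0.109. Of 31 measured integrins and adhesion genes, 6 were higher in TS2 and 2 in TS1, and adjusted over the list alone 7 and 2 passed. The integrin chains Itgal, Itga2 and Itgb7 were higher in TS2 by 3.26, 3.19 and 2.76, with an adjusted p of 0.00369 for Itgal. The tetraspanin Cd82 was higher by 2.92 (adjusted p = 0.0298), a call lost without TS2 A (adjusted p = 0.132), without TS2 B (adjusted p = 0.102) and with a robust prior variance (adjusted p = 0.0668). Higher in TS1 were Ncam1 and Itga4, named after their values were seen. The adhesion list did not pass camera (adjusted p = 0.0573), nor camera with an estimated correlation (adjusted p = 0.250), while fry in one direction gave adjusted p = 0.0182. It passed camera without TS2 A (adjusted p = 0.0173), with an intensity trend in the prior variance (adjusted p = 0.0480), with the replicate block (adjusted p = 0.0452) and with the dimmest 30% or 50% of probe sets left out (adjusted p = 0.0218 and 0.00309).

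**Figure D3:**
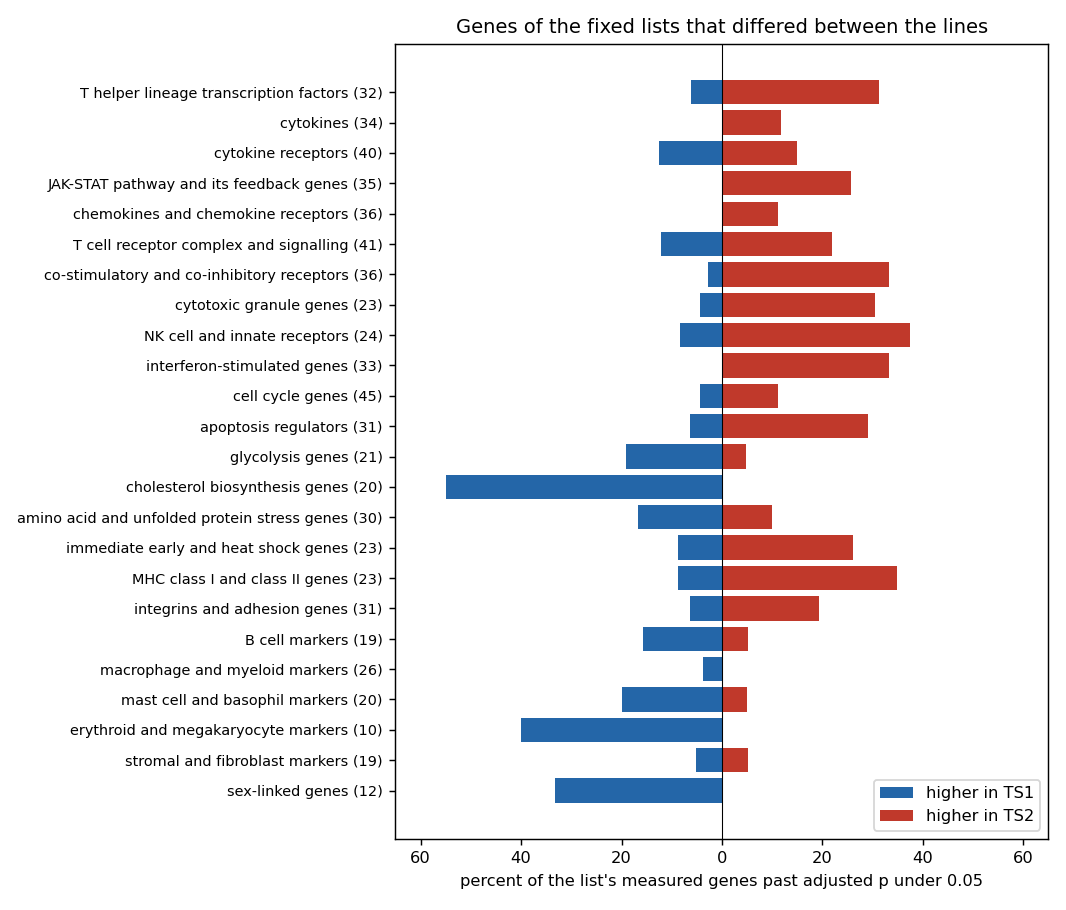
Percent of the measured genes of each of 24 fixed lists (x axis; y axis, list with the number measured in parentheses) that passed an adjusted p of 0.05, higher in TS1 to the left in blue and higher in TS2 to the right in red. Of 20 cholesterol biosynthesis genes 11 were higher in TS1, and of 33 interferon-stimulated genes 11 were higher in TS2. Of all 19939 genes 2691 passed, a larger share than of the cytokines (11.8%), chemokine genes (11.1%), stromal markers (10.5%) and myeloid markers (3.85%).

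Markers of other blood cells and of stroma were examined in the same way. Of 20 measured mast cell and basophil markers, 1 was higher in TS2 and 4 in TS1, and adjusted over the list alone 2 and 4 passed. Gata2, a transcription factor of blood progenitors and mast cells, was higher in TS1 by 25.1-fold (SE 0.18 on the log2 scale, adjusted p = 0.000411). Slc18a2, a vesicle transporter of monoamines, was higher in TS1 by 12.1-fold, and the receptor Kit by 3.73-fold. The last of the 4 was Gata1, named after its values were seen. Hpgds, a prostaglandin D synthase, was higher in TS2 by 4.42 (SE 0.17, adjusted p = 0.000405). Some markers were bright in both lines. Gata1 ran from 11.61 on TS1 A to 10.01 on TS2 B. Fcer1a and Srgn lay at 12.69 to 13.43 over the arrays, and Cpa3 at 7.95 to 9.13. Ms4a2, Tpsab1, Tpsb2, Mrgprb1, Mrgprb2, Hdc and Mitf lay lower, at 3.58 to 6.71. Apart from Gata1 these genes did not pass, and they are named after their values were seen. What these levels mean for the identity of the lines was not tested. Cma1, Mcpt1, Mcpt2, Mcpt4 and Mcpt8, mast cell protease genes of the list that were named after their values were seen, were brighter on TS2 B than on TS2 A, by 9.59-fold for Cma1 up to 26.6-fold for Mcpt1, and did not pass between the lines (adjusted p = 0.0773 to 0.323). As a list these markers did not pass camera (adjusted p = 0.945), whose direction was downward while their mean difference was 0.57 and their median 0.061. Of 10 measured erythroid and megakaryocyte markers, 0 were higher in TS2 and 4 in TS1 by limma (0 and 4 at an unadjusted p under 0.05), the same counts as adjusted over the list alone. They were Epor, the erythropoietin receptor, at -1.66 (SE 0.093, adjusted p = 0.00113), Klf1 at -1.11, Itga2b at -1.08 and Tfrc, the transferrin receptor of many dividing cells, at -1.004. Camera placed this list downward in TS2 (adjusted p = 0.0102), but not with an estimated correlation (adjusted p = 0.240).

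Of 19 measured B cell markers, 1 was higher in TS2 and 3 in TS1, the same counts as adjusted over the list alone. Cr2, a complement receptor, was higher in TS1 by 5.02-fold (adjusted p = 0.000748), Bank1 by 2.69-fold (adjusted p = 0.00899) and Ebf1 by 2.25-fold (adjusted p = 0.0135), while Pou2af1 was higher in TS2 by 0.96 (adjusted p = 0.0388). Bank1 lost its call without TS2 A (adjusted p = 0.0513), Ebf1 without TS1 B (adjusted p = 0.0561) and Pou2af1 without TS1 A (adjusted p = 0.118), TS1 B (adjusted p = 0.0991) or TS2 A (adjusted p = 0.0923) and with the replicate block (adjusted p = 0.0768). The B cell list did not pass camera (adjusted p = 0.936, upward), and its median of 0.052 and its mean of -0.15 differed in sign. Of 26 measured macrophage and myeloid markers, Cd68 alone passed, at -0.64 (adjusted p = 0.0261), and 0 passed limma adjusted over the list alone, with 3 at an unadjusted p under 0.05. Cd68 lost its call without TS1 A (adjusted p = 0.0702), TS2 A (adjusted p = 0.0883) or TS2 B (adjusted p = 0.136) and after quantile normalization (adjusted p = 0.0534). The myeloid list did not pass camera (adjusted p = 0.892), whose direction was downward while the mean difference was 0.071 and the median 0.024. Of 19 measured stromal and fibroblast markers, Vim, which encodes vimentin, was higher in TS2 by 1.14 (SE 0.092, adjusted p = 0.0032) and Pdgfra was higher in TS1 by 3.44-fold (adjusted p = 0.0325), the same 2 as adjusted over the list alone. The call of Pdgfra was lost without TS1 B (adjusted p = 0.0572), TS2 A (adjusted p = 0.141) or TS2 B (adjusted p = 0.0781). The stromal list did not pass camera (adjusted p = 0.637, upward), and its median of 0.048 and its mean of -0.071 differed in sign.

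Of 12 measured sex-linked genes, 0 were higher in TS2 and 4 in TS1 by limma (1 and 5 at an unadjusted p under 0.05), and adjusted over the list alone 0 and 5 passed. Xist had a log2 intensity of 11.52 ± 0.029 (SD, n = 2) in TS1 and 4.92 ± 0.17 (SD, n = 2) in TS2. Kdm5c and Kdm6a, which escape X inactivation, differed by -1.08 (SE 0.087, adjusted p = 0.00323) and -0.98 (SE 0.092, adjusted p = 0.00493). Eif2s3x, a translation factor gene that also escapes, differed by -0.54 (adjusted p = 0.0217), a call lost without TS1 B (adjusted p = 0.0717), TS2 A (adjusted p = 0.129) or TS2 B (adjusted p = 0.115) and with the replicate block (adjusted p = 0.0567). None of the measured Y-linked genes passed. Of these, named after their values were seen, Kdm5d, Eif2s3y and Uty lay at 4.14, 3.58 and 4.02 in TS1 and 4.39, 3.49 and 4.08 in TS2, and Sry was the brightest, at 6.88 on TS1 A up to 7.34 on TS2 B. Camera placed the list downward in TS2 (adjusted p = 0.0144), but not with an estimated correlation (adjusted p = 0.240).

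In total, camera called 18 of the 24 lists, 13 upward and 5 downward in TS2, with a preset correlation of 0.01 between genes. With an estimated correlation it called 0 of them, with 0 at an unadjusted p under 0.05. On simulated data of this design, the estimated correlation called a list shifted by 0.5 in 0 of 20 simulations and the preset one in 20 of 20. The simulated genes were drawn independently, so this cannot show how the preset value performs where genes of a list move together. The correlation estimated from the data ran from -0.078 for the sex-linked genes to 0.37 for the cholesterol biosynthesis genes. Neither setting can therefore decide which of the 18 calls hold. Tested against no change at all with fry, 18 lists moved on balance in one direction and 23 changed in either direction.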

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

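Against the main count of 2691 genes, the counts with an intensity trend or robust prior variance, centring, quantile normalization, a filter on dim probe sets or the mean of a gene's probe sets ran from 2431 to 2900. The count fell to 807 at an adjusted p under 0.01 and to 0 without moderated variances (4156 at an unadjusted p under 0.05), where 2 residual degrees of freedom per gene are left. Leaving out 1 array gave 980 to 2198 genes. The count of 1035 genes at least 2-fold apart ran from 836 to 1168 with 1 array left out, was 320 when tested against a 2-fold minimum, and 0 without moderation (855 at an unadjusted p under 0.05). Quantile normalization moved the split of calls to 1114 higher in TS2 and 1317 higher in TS1, and over all alternatives that called genes the share higher in TS2 ran from 35.3% to 45.8%, against 37.4%. Of T cell receptor segments, 0 or 1 passed with 1 array left out, and 1 passed with a robust prior variance, centring, quantile normalization or a filter on dim probe sets. The first principal component held 84.0% of the variance over the upper 50% of the probe sets by mean, against 76.8%.

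Camera called 18 lists, and 15 to 19 with 1 array left out. It called 0 with an estimated correlation, 0 of them at an unadjusted p under 0.05. The B cell list had a median of 0.052, and fry's test in one direction put it downward (adjusted p = 0.0411, against 0.936 with camera and 0.00378 to 0.999 over its alternatives). Camera has no counterpart to the robust or unmoderated fits, so the lists have no value there. Of 106 called named genes, 72 had an adjusted p under 0.01 and 50 passed the test against a 2-fold minimum. Leaving out 1 array ended between 6 and 28 of those calls, and no moderation ended all. A robust prior variance ended those of Cd82, Lifr, Nkg7 and Sla, centring that of Bub1b, and quantile normalization those of Bub1b and Cd68. An intensity trend, the mean of a gene's probe sets and the filters on dim probe sets ended 0, but the filters left values for 105 and 96 of the genes. The letters A and B are shared by the lines, but no label says that they mark a shared day. The deviations of B from A correlated between the lines at 0.025 over all probe sets. With these 2 pairs, that value cannot show whether arrays of the same letter shared a day. With the replicate block, 1666 genes passed, 1606 of them among the 2691, and 980 genes passed with at least 2-fold, while camera called 19 lists and 6 calls of named genes ended, those of Ccne1, E2f2, Eif2s3x, Eno2, Pou2af1 and Socs3 (adjusted p = 0.0503 to 0.0931). The cause of these shifts was not tested. Signal over background was not examined. With 2 arrays per line, real differences can be missed: 66.4% of the simulated 2-fold changes were recovered, and smaller changes were not simulated. The simulations changed 200 of 19939 genes, against 2691 called in the data, so the recovery there can differ.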

Other observations

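The tests of the mast cell protease genes and of TS1 A were chosen after the result was seen. Those of chromosome 8 were written before their own outcome was seen, but for a shift that was already known. The comparison of chromosomes was not part of the plan made before the data were examined.

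Genes of most chromosomes were shifted as sets against the other genes. Over genes with a mean log2 intensity of at least 8, 18 of 20 chromosomes, all but 2 and 5, had an adjusted permutation p under 0.05, and 15 of these kept 1 sign in every array pair. Chromosome 8 stood highest: its 427 genes had a median difference 0.42 above that of the other genes, and 115 of them were called higher in TS2 against 10 higher in TS1. Random sets matched on intensity gave -0.042 to 0.038 (permutation p = 2e-04, the smallest that 10000 sets can give), a test across genes, which are not replicates. The shift was 0.40 to 0.44 in each pair of a TS1 and a TS2 array. The shifts of chromosomes 4, 14, 15, 16 and X were -0.23, -0.22, -0.17, -0.23 and -0.20, and that of chromosome 3 was 0.15. Chromosomes 1, 7, 9, 10, 12, 13 and 18 were shifted by 0.051 for chromosome 1 up to 0.093 for chromosome 7, and chromosome 6 by -0.088. The medians of chromosomes 1, 7, 9, 10, 12, 13 and 18 themselves were negative, from -0.055 for chromosome 1 to -0.014 for chromosome 12. These chromosomes stood higher only against the other genes. The shifts of chromosomes 11, 17 and 19 were -0.093, -0.090 and -0.098 and changed sign between array pairs.

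An intensity-dependent bias between the arrays is argued against for chromosome 8, because its shift stayed at 0.42 after a smooth trend on intensity was removed, above the 0.041 of random sets. Unequal copy number of the whole chromosome between the lines may account for it: each of 4 equal blocks of its genes, in gene order, was shifted upward, the lowest by 0.32 and the highest by 0.47, where random sets reach 0.073. This stays a hypothesis, since no DNA was measured and GC content and regulation that spans a chromosome were not tested. The blocks divide the same genes whose shift was already known, so they show only that the shift is spread along the chromosome.

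The duplicates of TS2 differed in a cluster of mast cell protease genes. Ctsg was 57.6-fold, Mcpt1 26.6-fold, Mcpt2 15.2-fold, Mcpt8 13.4-fold, Mcpt4 11.3-fold and Cma1 9.59-fold brighter on TS2 B than on TS2 A, and these 6 genes neighbour each other. Mast cells or basophils mixed into the TS2 B culture are argued against. Of 11 such markers outside the cluster with a log2 intensity under 9 on TS2 A, 0 rose 2-fold. Their differences had a median of -0.077 and a range of -0.96 to 0.39. The lowest of them was Cpa3, a granule protease of mast cells encoded elsewhere, at 8.91 on TS2 A and 7.95 on TS2 B. Of 13 neighbouring genes outside the cluster 0 rose 2-fold, but the largest differences, 0.94 for Gzmb, 0.82 for Ripk3 and 0.68 for Gzmc, were upward as well. The genes of this paragraph are named after their values were seen. Cross-hybridisation between near-identical protease probe sets cannot be told apart from separate rises of the 6 genes, because no probe sequences were used, and no biological explanation was tested.

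The duplicates of TS1 differed as well. Of 221 genes at least 2-fold apart between them, TS1 A lay on the side of TS2 for 158. Among the 158 were Cd3g (10.52 on TS1 A, 6.07 on TS1 B), Il6 (8.51 and 5.34) and Il2ra (7.74 and 4.89). Cd3g, Il6 and Il2ra are named after their values were seen. TS2 cells mixed into the TS1 A culture are argued against as the cause of the whole pattern. Over 26 genes at least 16-fold higher in TS2 than on TS1 B and above a log2 intensity of 10 in TS2, the median share of TS2 signal that TS1 A implies was 2.08% (bootstrap interval 0.291% to 7.04%). The shares of single genes ran from -0.975% for Entpd1 to 61.8% for Cd3g. At the upper bound, that share would move 16 of the 158 genes 2-fold, none of them among the 62 that were lower on TS1 A, for which it would have to be at least 50.9%. A share that large would raise all 26 genes on TS1 A. However, 10 of them imply a share under 0.5%, among them Cd3e (0.037%) and Ptprc (0.0077%). These values argue against it for the 16 genes as well, while a smaller share of TS2 cells stays open. A difference in culture state or in the mix of TS1 cells stays open, and no biological explanation was tested.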
